A study of Mus musculus with 4 samples.

How the data were processed

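Immunopurified RNA (2 IP libraries) and total RNA (2 input libraries) were measured in cortex of adult transgenic mice of the NIDA030 line, in which Rpl10a carries an EGFP tag. Per the labels' protocols, tagged polysomes were captured from homogenised cortex with anti-EGFP antibodies on magnetic beads. Per the submitters' processing notes, STAR 2.0.0e, HTSeq and the mm10 build were used. The annotation, the strand setting and the library kit are not given in the sources used here. The deposited values are whole-number read counts per gene, not normalised, with 1 file per library. Sample descriptions place both IP libraries on lane 1 and both input libraries on lane 2, so lane and group cannot be told apart.

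Each file held 32531 gene names, 5 HTSeq summary lines and a line named unknown, which held 0, 0, 2 and 2 counts in IP 2, IP 4, input 2 and input 4. The lines that name no gene were left out of library sizes and tests. Reads outside any annotated feature were 7.31%, 7.54%, 14.9% and 13.5% of all records in that order, ambiguous reads 1.54%, 1.54%, 5.07% and 5.09%, and reads without a unique alignment 37.0%, 38.0%, 32.1% and 30.7%. Because reads aligned to several places were not assigned to genes, genes with close copies, such as ribosomal protein genes with pseudogenes, were undercounted. Reads of overlapping genes may also have been dropped or, if counted without strand, shared between antisense partners. Among the genes named from the lists, such overlaps are annotated at Nefm, Map2, Sv2b, Lhx6, Dlx1, Penk, Ntng2, Hs3st4, Lef1, Glul, Slc1a2, Mobp, Trf, Pclo, Grin1, Grm2 and Atp5f1, whose values are uncertain to that extent.

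Replicates were compared before use. The chi-square per degree of freedom between replicates was 24.3 for IP and 16.5 for input, far above sampling noise, so no library was a copy of another. The correlation of log2 CPM across genes, which are not independent replicates, was 0.995 within IP, 0.995 within input and 0.969 to 0.971 between the groups.

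Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation (factors 0.919, 0.909, 1.10 and 1.09), filterByExpr by group (minimum count 10, minimum total 15), and the quasi-likelihood test of IP against input without a block. Of 21923 genes with counts, 16600 were tested. The common dispersion gave a biological coefficient of variation of 12.5%, with 2 residual and 16.8 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and all tests were two-sided. CPM values are normalised by TMM-scaled library size.

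Gene lists were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated correlation. With an estimated correlation camera is limited to the 2 residual degrees of freedom of the fit, so that setting had little power. A call lost there does not argue against a list. Of 46 lists, 45 had at least 3 members tested. The list of mitochondrially encoded genes had 0 names in the files and was not tested. Counts are given over all genes and adjusted over the list alone. Some genes belong to more than 1 list, and many markers are also expressed by other cells of cortex.

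The named genes followed a fixed rule: Cbln1 and Rpl10a always, the 12 genes with the largest positive and the 12 with the largest negative fold change among called genes with a mean of at least 5 CPM and no predicted-model name, and up to 4 called members of each list with the largest absolute fold change and a mean of at least 5 CPM. Where no member passed, up to 2 abundant members were taken, and cell class lists also gave their most abundant member. Some genes that the rule takes are not reported here. The model, lists, rule and alternatives were fixed before the data were examined, except where a later choice is stated.

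Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, library sizes alone, no filter and a stricter filter on low counts, a test against a log2 fold change of 1, thinning to the smallest library, a replicate block, leaving out each library, and leaving out mitochondrial and ribosomal protein genes. A correction for GC content and transcript length, and runs without Rn45s or without the 5 genes that stood apart, were added after seeing the data. Coordinates, biotypes, GC content and lengths came from GENCODE vM21 on GRCm38, the assembly also called mm10. Of the 32531 names, 23113 matched by symbol, 727 through a synonym, and 8691 did not match. Sequences were compared with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9.

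The method was tested on simulated data with the 16600 genes and library sizes of the IP and input comparison. Changed genes were drawn only from those with a mean of at least 5 CPM, so recovery below that level was not tested. The method recovered 72% of genes changed 1.5-fold, 96% of those changed 2-fold, and 100% of those changed 4-fold and 8-fold (50 genes each). There were 5 false calls among 16400 unchanged genes. In the data only 8995 genes did not pass the threshold, so far fewer genes changed in the simulation. These rates need not carry over to the data.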

Results

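Polysomal and total RNA were measured in the cerebral cortex of adult mice carrying a Cbln1-driven transgene for the ribosomal protein Rpl10a fused to EGFP (line NIDA030). In translating ribosome affinity purification, ribosomes of the cells that express the tagged protein are captured with an anti-EGFP antibody, and the RNA bound to them is sequenced. Of the 4 libraries, 2 held immunopurified RNA (IP) and 2 held total RNA of cortex homogenate (input), numbered 2 and 4 in each group. Counts assigned to genes numbered 41334423 in IP 2, 47567384 in IP 4, 41385301 in input 2 and 39750468 in input 4, over 18639, 18753, 20429 and 20350 genes. A floor of 3 counts corresponded to 0.0660 to 0.0790 CPM (counts scaled by normalised library size), and such floors cover counting error only. The precursor of the ribosomal RNAs, Rn45s, took 6.58% and 7.55% of the gene counts in IP and 5.49% and 4.55% in input. The labels do not say whether libraries of one group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part. Xist, the noncoding RNA of the inactive X chromosome, differed between the numbers, with 0 and 20 counts in IP 2 and IP 4 and 2 and 132 counts in input 2 and input 4.

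Cbln1, which encodes the secreted synaptic organiser cerebellin 1 and whose regulatory sequence drives the tag, was 8.19-fold higher in IP than in input. Its normalised abundance was 84.0 ± 21.7 CPM in IP and 10.2 ± 2.39 CPM in input (SD, n = 2 each), from 3773 and 2968 counts in IP and 542 and 370 counts in input. The log2 fold change was 3.03 with a standard error of 0.17 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.39e-10), and both IP libraries lay above both input libraries. Cbln1 (ENSMUSG00000031654.16) is a protein-coding gene on the minus strand of chromosome 8, from 87468405 to 87472609 on GRCm38. Rpl10a, the ribosomal protein gene used for the tag, was counted at 3.01 ± 0.135 CPM in IP and 6.98 ± 0.226 CPM in input, a log2 fold change of -1.21 (SE 0.24, edgeR adjusted p = 0.000358). Reads from Rpl10a that also align to its pseudogene copies are not in these counts, and an antisense gene overlaps its exons, so its value is uncertain.

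**Figure D1:**
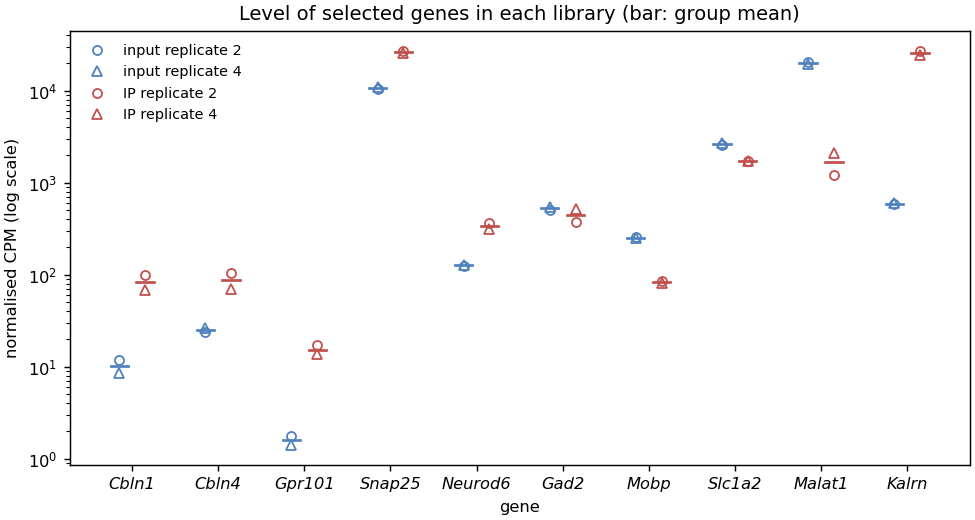
Normalised abundance in CPM on a log axis for 10 genes in each library, with circles for replicate 2, triangles for replicate 4, and bars at the mean of IP (red) and input (blue). Cbln1 averaged 84.0 CPM in IP and 10.2 CPM in input, and Malat1 averaged 1660 CPM in IP and 19893 CPM in input.

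Among genes with a mean of at least 5 CPM, 5 were more than 20-fold higher in IP and stood far above the rest. Kalrn, a guanine nucleotide exchange factor of dendritic spines, stood at 25736 ± 1809 CPM in IP against 588 ± 11.4 CPM in input (SD, n = 2 each), a 43.8-fold difference. Atg7, an enzyme of autophagosome formation, was 47.3-fold higher, Lrguk, a protein with a guanylate kinase domain, 36.7-fold, Yeats2, a reader of histone acylation, 36.2-fold, and Ubr3, a ubiquitin ligase, 22.9-fold. These 5 genes made up 3.24% and 2.97% of the gene counts in IP and 0.0964% and 0.101% in input. Gpr101, an orphan receptor, was 9.59-fold higher, and Prpf8, a core protein of the spliceosome, 7.84-fold. Tmem255b, Micall2 and Uaca were 15.7-fold, 13.7-fold and 10.1-fold higher, and Sh2d3c, an adaptor protein gene, 8.32-fold. Single libraries weighed on 2 of these values: Tmem255b was 10.2-fold higher without IP 2, and Micall2 was 8.77-fold higher without IP 4. Tmem255b and Sh2d3c overlap exons of genes on the opposite strand, whose reads could not be told apart without strand.

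The 5 genes lie on 3 chromosomes of GRCm38 and are all protein-coding. Kalrn (ENSMUSG00000061751.16) spans 33969073 to 34573532 on the minus strand of chromosome 16, and Yeats2 (ENSMUSG00000041215.16) spans 20141063 to 20232573 on its plus strand. Atg7 (ENSMUSG00000030314.16) spans 114643097 to 114860614 and Lrguk (ENSMUSG00000056215.13) spans 34029448 to 34134034, both on the plus strand of chromosome 6. Ubr3 (ENSMUSG00000044308.17) spans 69897246 to 70024013 on the plus strand of chromosome 2.

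Among the transcripts most reduced in IP were several noncoding RNAs. Malat1, a long noncoding RNA of nuclear speckles, was 11.98-fold lower, at 1660 ± 653 CPM in IP and 19893 ± 595 CPM in input (SD, n = 2 each). Of the 12 genes with the lowest fold changes by the fixed rule, 11 carried only a sequence accession as their name and had no annotated biotype, with log2 fold changes from -5.43 to -3.63, and together they held 2.08% of the input counts. Without IP 4, 3 of them moved by more than 1.5 times, to -5.91, -5.78 and -5.95. The 12 lowest genes with a gene symbol were therefore also taken, a choice made after the values were seen. After Malat1 they were Meg3 (8.68-fold lower), Gdap10 (8.10-fold), Kcnq1ot1 (8.05-fold), Miat (7.86-fold), Snhg11 (7.45-fold), Ftx (7.32-fold), Firre (7.03-fold), Cdr1 (6.66-fold), Neat1 (6.50-fold), Trank1 (6.28-fold) and Amy1 (6.18-fold). Meg3 is a maternally expressed imprinted noncoding RNA, Kcnq1ot1 an antisense noncoding RNA of an imprinted domain, and Neat1 the scaffold of paraspeckles. The annotation gives Snhg11, Cdr1, Trank1 and Amy1 as protein-coding. Overlapping or antisense genes are annotated at Malat1, Meg3, Kcnq1ot1, Miat, Snhg11, Ftx, Cdr1, Neat1 and Amy1, so their counts are uncertain to that extent.

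Across the genome, 3886 of 16600 genes tested rose in IP and 3719 fell, and 8995 did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A fold change of at least 2 was estimated for 609 of the higher and 1779 of the lower genes. Among the 10681 genes with a mean of at least 5 CPM, 3663 rose and 2185 fell, with 467 and 387 of them at least 2-fold. The direction went with abundance: below 1 CPM 35 of 2866 genes rose and 772 fell. From 50 to 500 CPM 1592 of 3626 rose and 761 fell, and from 500 CPM upward 156 of 247 rose and 37 fell. Of 14274 protein-coding genes tested, 3832 rose and 2503 fell. Of 1467 genes named only by a sequence accession, 39 rose and 796 fell, so the near-even split did not hold within these classes. In 68 of the genes that fell, neither IP library held a count. Both IP libraries lay on the same side of both input libraries in 73.0% of the genes tested, where chance gives 33.3%. The split between directions depended on the scaling: with library sizes alone, 2151 genes rose and 5910 fell, 26.7% higher against 51.1%, and the median of all genes moved by -0.26 on the log2 scale. Tested against a log2 fold change of 1, genes higher in IP numbered 172 and genes lower in IP numbered 675.

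**Figure D2:**
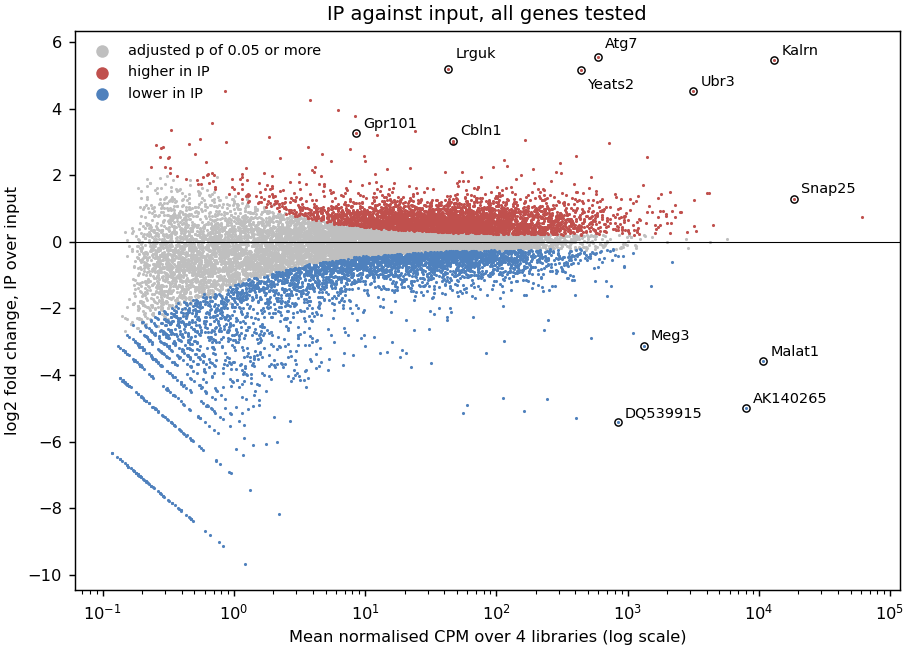
Log2 fold change of IP over input against mean CPM on a log axis for the 16600 genes tested, one point per gene, with genes that rose in red, genes that fell in blue and the others in grey. Kalrn, Atg7, Lrguk, Yeats2 and Ubr3 lie above all other genes with a mean of at least 5 CPM, the next of which was 15.7-fold higher in IP.

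Genes of neurons in general rose in IP. Of the 24 pan-neuronal genes, 22 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.86. Nefm, a neurofilament subunit, rose by 1.83 (SE 0.11), Tubb3, the neuronal tubulin, by 1.60 (SE 0.10), and Vsnl1, a neuronal calcium sensor, by 1.48 (SE 0.09). Snap25, a component of the vesicle fusion complex, stood at 26254 ± 1120 CPM in IP and 10721 ± 270 CPM in input (SD, n = 2 each), and Map2, a dendritic microtubule protein, fell by 1.63 (SE 0.09). The list stood above other genes by camera on the edgeR fit (adjusted p = 2.37e-18, and adjusted p = 0.741 with an estimated correlation). Camera set it against genes of all levels, whereas abundant genes in general rose more often: 156 of 247 genes from 500 CPM upward and 1592 of 3626 from 50 to 500 CPM.

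Markers of most glial and vascular cell types moved in both directions, whereas ependymal and erythroid markers held no gene that rose. Of 22 oligodendrocyte genes, 4 rose and 11 fell (median -0.25): the myelin protein gene Mobp fell by 1.61 (SE 0.09), whereas Trf, the transferrin gene, rose by 0.98 (SE 0.10). Of 22 astrocyte genes, 8 rose and 9 fell, with a median of -0.16, a mean of 0.05 and an upward camera direction. Glul, the glutamine synthetase, rose by 0.84 (SE 0.10) and Acsbg1 by 1.09 (SE 0.13), whereas Slc1a2, the main glutamate transporter, fell by 0.61 (SE 0.08). Of 15 oligodendrocyte precursor genes 1 rose and 5 fell (median -0.21), with the proteoglycan gene Cspg4 higher by 2.03 (SE 0.21) and Vcan lower, at -1.65 (SE 0.19). In the microglia and macrophage list 1 of 19 genes rose and 3 fell (median -0.16), and in the pericyte list 2 of 16 rose and 3 fell (median -0.51). Of 15 fibroblast genes 2 rose and 5 fell (median -0.06), and Dcn, the proteoglycan decorin, was 7.76-fold higher at 83.1 ± 5.14 CPM in IP against 10.7 ± 0.363 CPM in input (SD, n = 2 each). Those counts were the same when adjusted over the list alone. Of 19 endothelial genes 4 rose and 1 fell, or 2 and 0 adjusted over the list alone, with a median of 0.04 that turned to -0.22 with library sizes alone and a mean of -0.16. The 7 ependymal genes held 2 that fell, or 0 adjusted over the list alone (median -0.54), and all 4 erythroid genes fell by both adjustments (median -2.004). None of these lists stood apart from other genes by camera.

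Set directly against each other, the 61 genes pooled from the pan-neuronal, glutamatergic and GABAergic lists lay above the 134 genes of glial, vascular and blood cells. Of the neuronal genes 35 rose and 11 fell (median 0.31), and of the others 21 rose and 42 fell (median -0.23). The medians differed by 0.54 (camera on the edgeR fit, p = 9.47e-06, and p = 0.102 with an estimated correlation). This held for the pooled genes and not for each list. The GABAergic median of -0.24 lay below the oligodendrocyte precursor, astrocyte, microglia, fibroblast and endothelial medians. With library sizes alone the medians of the pools were 0.05 and -0.49. The pools were not matched for abundance.

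Glutamatergic markers lay above GABAergic markers. Of 18 glutamatergic genes, 10 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.28. Neurod6, a transcription factor of cortical excitatory neurons, rose by 1.42 (SE 0.10), Sv2b, a synaptic vesicle protein, by 0.67 (SE 0.08), and Camk2a, a postsynaptic kinase, by 0.48 (SE 0.08). Of 19 GABAergic genes, 3 rose and 8 fell, or 4 and 8 adjusted over the list alone, with a median of -0.24. Dlx6os1, a noncoding RNA of the forebrain Dlx locus, fell by 2.05 (SE 0.21), and the interneuron transcription factor genes Lhx6, Dlx5 and Dlx1 fell too, with log2 fold changes of -1.18, -0.96 and -0.92. Gad2, which makes GABA, had a log2 fold change of -0.24 that did not pass (edgeR adjusted p = 0.0922). The medians differed by -0.52 (camera on the edgeR fit, p = 0.00329, and p = 0.157 with an estimated correlation). Neither list alone stood apart from other genes (adjusted p = 0.0998 and 0.237), although the glutamatergic list was called with DESeq2 (adjusted p = 0.0309) and without a filter on low counts (adjusted p = 0.0107). With library sizes alone, 5 glutamatergic genes rose and 3 fell (median 0.02), and 1 GABAergic gene rose and 11 fell (median -0.50).

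Among subclasses of cortical neurons, the layer 6 intratelencephalic and Car3 list stood above other genes. Of its 13 genes 7 rose and 1 fell, also when adjusted over the list alone, with a median of 0.67. Nr4a2, an orphan nuclear receptor, rose by 1.27 (SE 0.10), Ntng2, a netrin-G adhesion protein, by 0.94 (SE 0.14), Oprk1, the kappa opioid receptor, by 0.91 (SE 0.20), and Penk, the proenkephalin gene, by 0.78 (SE 0.11). Its adjusted p by camera was 0.0211, and adjusted p = 0.847 with an estimated correlation. With library sizes alone 6 of its genes rose and 2 fell (median 0.41). No other subclass list was called. Nr4a2 is also in the immediate-early and retrosplenial lists, and Penk in the Vip, striatal and neuropeptide lists.

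Single markers of the other layers moved apart. Of 17 layer 6 corticothalamic genes 3 rose and 5 fell (median -0.07), with the neurotensin receptor gene Ntsr1 higher by 2.18 (SE 0.20) and Hs3st4 lower, at -1.20. The layer 5 intratelencephalic list had 7 higher and 2 lower of 13 (median 0.35), with Il1rapl2 at 1.60 (SE 0.18). Those counts were the same adjusted over the list alone. Of 12 layer 4 genes 3 rose and 5 fell, or 3 and 6 adjusted over the list alone (median -0.30), and Rorb, a nuclear receptor of that layer, fell by 0.96. Of 14 layer 6b genes 2 rose and 2 fell, or 2 and 0 adjusted over the list alone, with a median of -0.14 and an upward camera direction. The layer 2/3 list (4 higher and 4 lower of 14), the layer 5 extratelencephalic list (6 and 4 of 18) and the layer 5/6 near-projecting list (4 and 3 of 12) had medians of 0.11, 0.07 and 0.14, which turned negative with library sizes alone, and the same counts adjusted over the list alone.

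Among interneuron subclasses, 1 of 15 Pvalb genes rose and 6 fell (median -0.33), and Pvalb itself fell by 0.52. The Sst list had 7 higher and 2 lower of 17, with Cbln4, a cerebellin made by Sst interneurons among others, higher by 1.81 (SE 0.15) and the neuropeptide gene Npy lower, at -0.85. Both pairs of counts were the same adjusted over the list alone. The Vip list had 3 higher and 3 lower of 14, or 2 and 1 adjusted over the list alone, and the Lamp5 list 1 and 3 of 13, or 1 and 2. The Sst, Vip and Lamp5 medians were 0.22, 0.14 and 0.13 and turned negative with library sizes alone.

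Markers of striatal projection neurons fell. Of 20 genes 12 fell and 1 rose, or 13 and 1 adjusted over the list alone. The median was -0.47 (camera on the edgeR fit, adjusted p = 0.0310, and adjusted p = 0.847 with an estimated correlation). The gene that rose was Penk, which is also in the layer 6 intratelencephalic and Car3 list. The log2 fold change was -1.24 (SE 0.22) for Drd2, a dopamine receptor, -1.14 (SE 0.23) for Adora2a, an adenosine receptor, -0.98 (SE 0.12) for Rgs9, a regulator of G protein signalling, and -0.92 (SE 0.11) for Meis2, a homeobox factor. The call was lost without IP 2 (adjusted p = 0.119) and without input 4 (adjusted p = 0.0694). Scaled by library sizes alone, 16 genes fell and 1 rose (median -0.73).

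Other regional lists were not called. The retrosplenial list, which contains Cbln1, had 8 higher and 4 lower of 14 (median 0.38), with Lef1, a Wnt pathway transcription factor, higher by 2.43 (SE 0.25). The thalamic list, which also contains Cbln1, had 6 higher and 5 lower of 17, or 6 and 6 adjusted over the list alone, with a median of -0.19, a mean of 0.20 and an upward camera direction. Tcf7l2, a thalamic transcription factor, fell by 1.04 (SE 0.17). Of 15 hippocampal genes 7 rose and 1 fell (median 0.42), with Fibcd1 at 1.77 (SE 0.22), and of 12 cerebellar and hindbrain genes 2 rose and 3 fell, with a median of 0.03 that turned negative with library sizes alone. The retrosplenial, hippocampal and cerebellar counts were the same adjusted over the list alone. The camera direction of the cerebellar list was downward, against a positive median and mean.

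Genes of transmitter release and of the activity response rose as groups. Of 32 synaptic vesicle and release genes 17 rose and 6 fell (median 0.37, camera adjusted p = 0.00837, and adjusted p = 0.847 with an estimated correlation). Nsf, the ATPase that recycles the fusion complex, rose by 1.44 (SE 0.08), whereas Pclo, a large scaffold of the active zone, fell by 1.60 (SE 0.09). This call was lost with library sizes alone (15 higher and 11 lower, median 0.11, adjusted p = 0.108) and without input 2 (adjusted p = 0.0854). Of 21 immediate-early genes 12 rose and 1 fell (median 0.46, camera adjusted p = 0.00267, and adjusted p = 0.847 with an estimated correlation). The nuclear receptor genes Nr4a1 and Nr4a3 each rose by 1.09 (SE 0.09 and 0.15) and Egr4, a zinc finger factor, by 1.06 (SE 0.11). With library sizes alone, 9 of the immediate-early genes rose and 4 fell (median 0.21). Both lists had the same counts adjusted over the list alone.

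Cerebellins and their partners held 6 genes that rose and 2 that fell of 18 (median 0.27, camera adjusted p = 0.112). Without IP 4 the list was called (adjusted p = 0.0253), although its median relative to all genes was then 0.08 against 0.31 with all libraries. Besides Cbln1 and Cbln4, Dcc, a netrin receptor, rose by 0.67 (SE 0.12) and Nptx2, a neuronal pentraxin, by 0.64 (SE 0.14). Of 73 neuropeptide and monoamine receptor genes 16 rose and 8 fell, with a median of 0.16 that turned negative with library sizes alone. Htr1a, a serotonin receptor, rose by 1.84 (SE 0.14) and Sstr2, a somatostatin receptor, by 1.13 (SE 0.15). Of 17 ionotropic glutamate receptor genes 1 rose and 5 fell (median -0.11), with Grin1 at 0.82 and Grik1 at -1.09. Of 7 metabotropic glutamate receptor genes 2 rose and 0 fell, with Grm2 at 1.04 and a median of 0.15 that turned negative with library sizes alone, and of 15 GABA receptor genes 1 rose and 6 fell (median -0.21). Potassium channels held 7 higher and 19 lower of 66 (median -0.16), including the noncoding Kcnq1ot1, which the name pattern also took. Of 14 sodium and HCN channel genes 2 rose and 4 fell (median -0.08), and of 23 calcium channel genes 4 rose and 6 fell (median -0.17). These counts were the same adjusted over the list alone. Of 22 neuropeptide genes 5 rose and 4 fell, or 5 and 3 adjusted over the list alone, with a median of 0.04 and a mean of -0.03. Of 30 postsynaptic density genes 9 rose and 10 fell, or 12 and 10 adjusted over the list alone (median 0.11), and Shank2, a scaffold protein, rose by 2.36 (SE 0.18). The neuropeptide and postsynaptic density medians turned negative with library sizes alone.

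Among housekeeping and technical groups, nuclear genes of oxidative phosphorylation rose. Of 91 such genes 53 rose and 3 fell, or 57 and 3 adjusted over the list alone, with a median of 0.39 (camera on the edgeR fit, adjusted p = 1.22e-07, and adjusted p = 0.847 with an estimated correlation). Atp5f1, an ATP synthase subunit, rose by 1.21 (SE 0.10), Uqcrfs1, a subunit of complex III, by 1.08 (SE 0.10), and Sdhb, a succinate dehydrogenase subunit, by 1.01 (SE 0.10). Of these genes 33 rose and 11 fell with library sizes alone (median 0.13). The list was not compared with genes of like abundance. Noncoding RNAs described as retained in the nucleus fell: 12 of 14 fell and 0 rose, or 13 and 0 adjusted over the list alone, with a median of -2.62 (adjusted p = 4.75e-25, and adjusted p = 0.741 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 3 rose and 20 fell, or 2 and 16 adjusted over the list alone (median -0.22, adjusted p = 0.237). Of 40 histone genes 7 rose and 3 fell, or 5 and 3 adjusted over the list alone (median 0.33, adjusted p = 0.674). Of the 45 lists tested, camera called 5 higher and 2 lower with its preset correlation, and 0 with an estimated correlation, where 8648 single genes had an unadjusted p under 0.05 by edgeR. The lowest unadjusted camera p with an estimated correlation was 0.0262, for the nuclear-retained noncoding RNAs. The 0 calls of that setting therefore carry little weight.

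**Figure D3:**
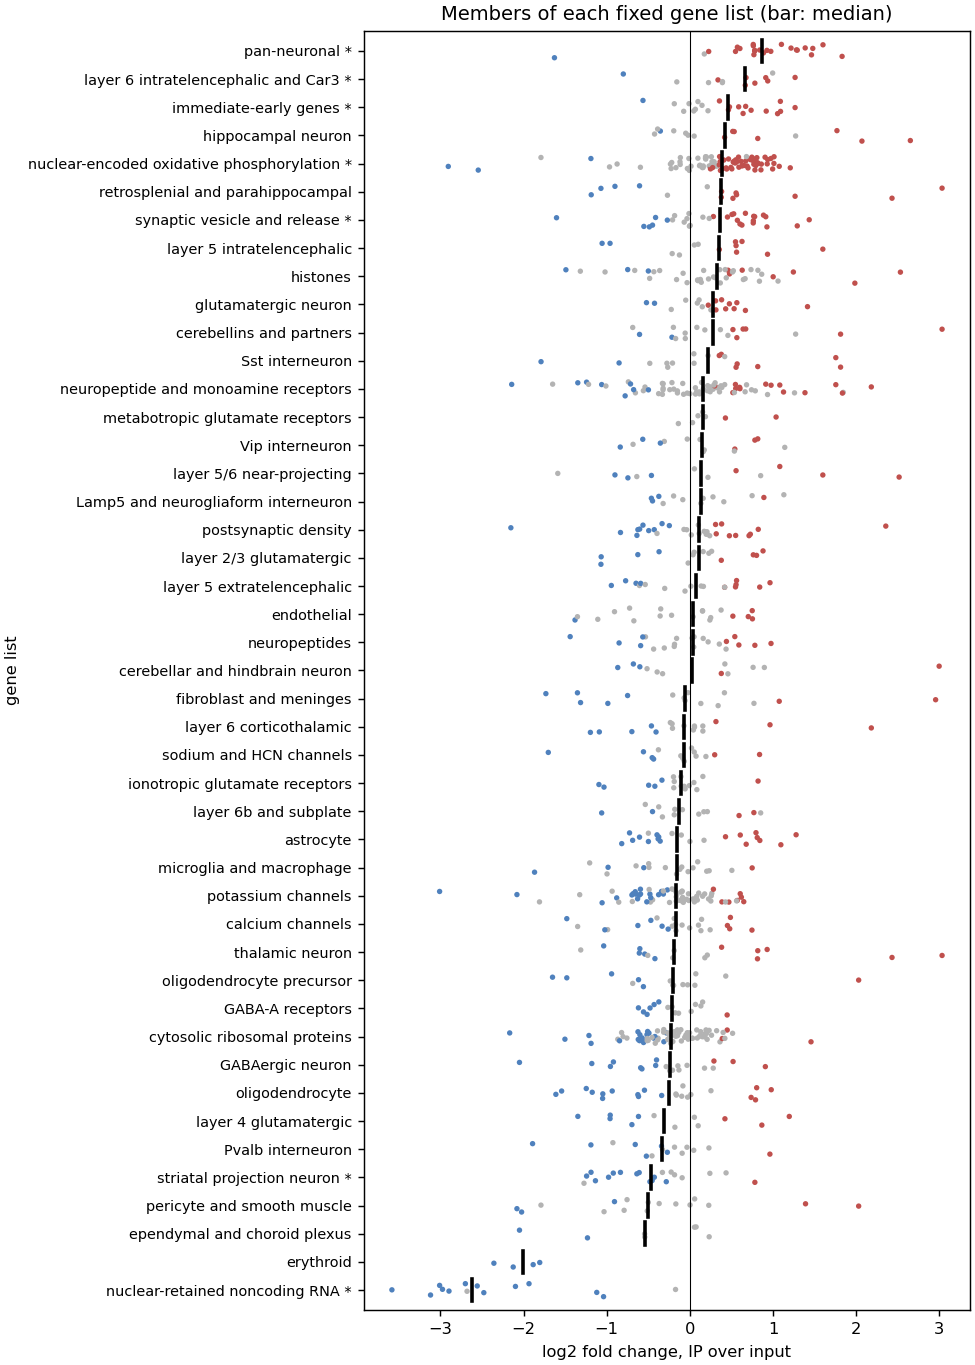
Log2 fold change of IP over input for the members of each gene list, with points for genes (red for higher, blue for lower, grey for not called), black bars for list medians and asterisks for lists called by camera with the preset correlation. The pan-neuronal median was 0.86 and that of the nuclear-retained noncoding RNAs -2.62, and 12 list medians near 0 turned negative when libraries were scaled by size alone.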

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

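The tests of the tagged cells, of sequencing lane and of the neuronal share were chosen after the results were seen, and the correction for GC content and transcript length was added after seeing the data. Reads without a unique alignment, which enter no gene count, made up 37.0% of records in IP 2 and 38.0% in IP 4, above the 32.1% and 30.7% of the inputs, and stand out as signal in data that the gene comparison does not use.

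Kalrn, Atg7, Lrguk, Yeats2 and Ubr3 were each more than 20-fold higher in IP, whereas the next gene with a mean of at least 5 CPM reached 15.7-fold. Between annotated transcripts of the 5 genes, 0 of the 10 gene pairs shared an alignment of at least 50 nt at 90% identity. This does not decide on shared sequence, since reads aligned to several places were not counted and sequence shared with other sources was not searched. A trend with GC content and length was argued against, since the median log2 fold change of the 5 genes after correction was 5.36, with a lowest value of 4.69. That these are transcripts of the tagged cells stays open: their median log2 ratio of IP 2 to IP 4 was 0.14 against 0.53 for Cbln1, but 1 library of each number cannot decide it. An RNA or DNA source peculiar to the IP, such as the construct or the beads, may also apply and was not tested.

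Pooled, the 61 genes of the pan-neuronal, glutamatergic and GABAergic lists lay above the 134 genes of glial, vascular and blood cells by 0.54 in median log2 fold change. However, the GABAergic median of -0.24 lay below the oligodendrocyte precursor, astrocyte, microglia, fibroblast and endothelial medians (-0.21, -0.16, -0.16, -0.06 and 0.04). A trend with GC content and length was argued against as the whole cause, since the difference was 0.52 after correction (p = 4.57e-05 by camera with its preset correlation). With an estimated correlation the call was lost both before (p = 0.102) and after it (p = 0.179). Sequencing lane and library preparation cannot be told apart from the group, because 0 lanes held libraries of both groups. A neuronal origin of the tagged polysomes, which the design names, stays open as well.

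Oxidative phosphorylation genes had short transcripts (median 1170.5 nt against 3390 nt for all genes) and rose in IP. After the GC and length correction their median relative to all genes was 0.46 (adjusted p = 6.89e-08 by camera with its preset correlation), which argues against that trend as the whole cause. With an estimated correlation the call was lost both before (adjusted p = 0.847) and after it (adjusted p = 0.855). A larger share of neuronal RNA in IP stays open and was not decided by any value: the list's median differed from the pan-neuronal median by -0.47, but the latter was the highest of all 45 lists tested, so any other list would have lain below it.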

How the results depend on the processing

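The correction for GC content and length and the runs without Rn45s or without the 5 genes that stood apart were chosen after seeing the data. With library sizes alone, 2151 genes were higher and 5910 lower, because this scaling moved the median of all genes by -0.26. Tested against a log2 fold change of 1, genes higher in IP numbered 172 and genes lower in IP numbered 675, a stricter question by construction. With an estimated correlation in camera, the neuron to glia difference of 0.54 had p = 0.102. With an estimated correlation in camera, the GABAergic to glutamatergic difference of -0.52 had p = 0.157. That setting called 0 lists against 7, but it is limited to the 2 residual degrees of freedom, and its lowest unadjusted camera p was 0.0262. The layer 6 intratelencephalic and Car3 list had an estimate of -0.037, below the preset 0.01, so a larger correlation does not explain its lost call. Long noncoding genes outside the fixed list, with an estimate of 0.0067, also had weaker evidence. The few residual degrees of freedom weaken every list in that setting, whatever its correlation. The other called lists had estimates of 0.074 to 0.425, so for them the part of a larger correlation cannot be told apart from this limit. Under DESeq2, 3749 genes were higher and 3162 lower; without a filter, 4104 and 3752; with a stricter one, 3544 and 3548; thinned, 3865 and 3708; with GC and length corrected, 3425 and 4128. Leaving out 1 library gave 3302 to 3622 higher and 2747 to 3616 lower, where the remaining lone library is assumed to vary like the other group. Calls shared with the reported result had the same sign in each setting that refits all genes; this was not counted for the test against a log2 fold change of 1. Replicate numbers are shared by 2 pairs only, so pairing was not established: the replicate block gave 4314 and 4037, and deviations of same-numbered libraries correlated at 0.0481 across all genes tested and at 0.244 across those with a mean of at least 20 CPM. No called gene, list or comparison reversed, whereas the medians of 12 lists that were not called and the fold of 1 named gene that was not called changed sign with library sizes alone. Some lists gained a call: glutamatergic with DESeq2 and without a filter, oligodendrocyte with library sizes alone and with the GC and length correction, erythroid without a filter and without IP 4, ribosomal proteins without input 4, and cerebellins and retrosplenial without IP 4. Without IP 4 the cerebellin median relative to all genes was 0.08 against 0.31 with all libraries. Of 180 named genes 153, and of 45 lists 32, kept their side of the threshold in all settings. Of the named genes 178 were called, and the rule took those with large fold changes, so their stability was favoured by the choice. At 39750468 to 47567384 counts per library, recovery of 1.5-fold changes was 72% in simulation among genes with a mean of at least 5 CPM. The simulation did not separate depth from the number of libraries.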

Other observations

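The tests of glycolytic enzymes, noncoding genes, long messenger RNAs and Xist were chosen after the fold changes that prompted them were seen, as were the tubulin genes. Glycolytic enzyme genes rose together: of 16 genes other than Aldoa, 14 rose and 1 fell, with a median log2 fold change of 1.01 (camera on the edgeR fit, p = 1.92e-15, and p = 0.0212 with an estimated correlation). Aldoa, an aldolase, rose by 1.71, Pkm, a pyruvate kinase, by 1.62, and Ldha, a lactate dehydrogenase, by 1.40, whereas Eno1 fell by 0.90. Of 12 genes for alpha and beta tubulins 11 rose and 0 fell, with a median of 1.46, and Tubb2a and Tuba1a rose by 2.06 and 1.73.

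Long noncoding RNA genes outside the fixed list were lower as a class. Of 643 such genes 323 fell and 4 rose, with a median of -1.09 (camera on the edgeR fit, p = 9.86e-13, and p = 0.0137 with an estimated correlation). A candidate explanation is that RNA not bound to ribosomes is depleted by the purification, which these data cannot test beyond the class effect.

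Map2, Pclo and Trank1, whose log2 fold changes were -1.63, -1.60 and -2.65, prompted a test of transcript length. Pclo and Trank1 have transcripts of at least 10000 nt, whereas the longest of Map2 was 6258 nt, so length in this sense leaves Map2 unexplained. The other 379 protein-coding genes with a transcript of at least 10000 nt had a median of -0.25 against 0.07 for the remaining protein-coding genes, with 56 higher and 161 lower (camera on the edgeR fit, p = 1.11e-07, and p = 0.296 with an estimated correlation). Shorter ranges shifted less. Protein-coding genes of 6000 to 8000 nt, the range of Map2, had a median of -0.07 (263 higher and 346 lower). Those of 8000 to 10000 nt had -0.11 (104 and 166). Not all long messages fell, since 56 of the 379 rose. Kalrn (10438 nt) and Lrguk (10475 nt) were 43.8-fold and 36.7-fold higher, but the source of their counts stays open. A loss of long messages during the purification may contribute for Pclo and Trank1. The call of the long genes was not kept with an estimated correlation.

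Xist, the noncoding RNA of the inactive X chromosome, had 0 counts in IP 2, 20 in IP 4, 2 in input 2 and 132 in input 4. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 97.6 CPM in IP 2, 67.1 in IP 4, 110 in input 2 and 63.1 in input 4. Replicate 4 thus had more Xist and less Y-linked signal in both fractions, which argues against a purely technical spread between replicates 2 and 4. The same animals behind IP and input of one number would give this order. Animals of both sexes in replicate 4 are a further possibility, but Xist reached only 3.05 CPM in input 4 and 0.463 CPM in IP 4. Whether so little Xist could go with the Y-linked difference was not tested. The labels state neither, and 2 pairs cannot decide these.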
